A study of Mus musculus with 240 samples.

How the data were processed

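The values as deposited are log10 ratios of 1 mouse to the pool of its strain and tissue, and per the labels they come from total RNA taken with Trizol and an RNeasy column, 1 round of reverse transcription and in vitro transcription to cRNA, and Cy3 and Cy5 labelling. The scanner software, background correction and normalization are not given in the sources used here. The unit was read from the values: they centre on 0, array medians run from -0.034 to 0.033 in log10, and 757 values (0.008%) sit at limits of -2 and 2. The base that makes the mean ratio of the most variable probes equal to 1 within a pool's own mice ran from 8.82 to 12.6, with a median of 10.4. No value was missing. The labels name no array batch, so none could enter a fit. One pool differs in name: for BTBR adipose tissue the labels call it a control pool of ob mice, which mice it holds was not settled here, and it cancels in every comparison within the strain.

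Each value was rescaled to log2. Of 39556 probes, 23283 (58.9%) could be given 1 gene symbol from the annotation used here, through the current symbol for 16574, a synonym for 6594, and the symbol kept as given for 115. The other 16273 were not analysed here. A gene with 2 or more probes (2869 genes) got the mean of its probes, and 17027 genes had 1, for 19896 genes in all. No filter on level was used, since a ratio to a pool gives no level.

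Each tissue was fitted on its own with limma, with a mean for each of 8 groups over its 40 arrays, so that all groups share 1 estimate of the spread, and with moderated variances by empirical Bayes. Comparisons were ob minus lean in each strain and age, the BTBR effect minus the B6 effect at each age, and 10 minus 4 weeks in lean mice averaged over the strains. Adjusted p values follow Benjamini and Hochberg over all genes, and tests are 2-sided. Lists were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the lists and 7 comparisons of a tissue. The same test with the correlation estimated from the residuals, and fry, stand beside it. Of 45 lists, 19 were tested in every tissue and the rest in tissues where they have a meaning. List scores are means over members, and score differences between tissues were tested by exact permutation over 63504 arrangements of the lean and ob labels.

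The lists, comparisons, tests, most alternatives and the rule for named genes were fixed before the data were examined. That rule names Lep and the tissue marker genes used for checks. It adds the 6 largest rises and 6 largest falls of each 10-week obesity effect among genes past the threshold whose groups do not overlap, 6 and 6 for the strain difference at 10 weeks, and 4 and 4 for age. For each list described it takes up to 4 members past the threshold with the largest change, or the 2 with the smallest p if none passes. Placeholder symbols were skipped, and the text prints a part of the genes so named. The fit without arrays that stand apart and the fit with an acinar score as a covariate were chosen after seeing the data.

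In 15 of 15 tissue pairs the deviations from the group means correlated more within a mouse than between mice. The median correlations were low, at 0.006 to 0.284 within a mouse and -0.088 to -0.006 between mice, and those of islets with another tissue were 0.075 or less. Of 43 mice, 36 have all 6 tissues. No 2 arrays were identical, and the highest correlation within a group was 0.897. The code was tested on simulated data with 19896 genes of which 200 were changed. In the 10-week BTBR comparison it found 92.5% to 100% of genes changed 2-fold and 70.1% to 94.0% of those changed 1.5-fold. For the strain difference at 10 weeks these were 77.6% to 97.0% and 50.7% to 83.6%. False calls over all comparisons were 2.34% to 9.09%, and with no change it called 0. Tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.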

Results

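Gene expression was measured on 240 arrays of 2 colours, each setting the RNA of 1 male mouse against a pool from its own strain and tissue. The mice came from 2 inbred strains, lean or carrying the ob mutation of Lep, the gene of the satiety hormone leptin. B6 mice are known to stay largely free of severe diabetes when made obese by this mutation, and BTBR mice to develop it. Pancreatic islets, liver, gonadal adipose tissue, gastrocnemius, soleus and hypothalamus were taken at 4 and 10 weeks of age, with 5 mice in each of 48 groups. An obesity effect is ob minus lean within a strain, in which the pool cancels; the level of one strain against the other was not measurable. A strain difference is the BTBR effect minus the B6 effect, so a gene higher or lower in BTBR by it differs in the effect of obesity and not in level. Values are log2 differences with the standard error (SE) of the fit after ±, n = 5 per group. A gene "rose", "fell" or "changed" where it passed an adjusted p of 0.05 among 19896 genes. The number of arrays limits the precision.

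The labels do not settle which way the ratio runs, and directions here are likely ones. Their first basis is the pool itself: over the mice that made it, a log ratio of mouse over pool averages below 0. Of 12 strain and tissue sets, 11 had most of their 200 most variable probes below 0. The exception was B6 hypothalamus, with 44.5% of these probes below 0. For BTBR adipose tissue, with 96.5%, the labels name a pool of ob mice, so that its place among the 11 assumes that the pool held the mice measured against it. With the sign turned, every rise reads as a fall of the same size, and the counts of higher and lower genes change places.

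Islets of 10-week B6 ob mice carried higher transcripts of cell division and of the secretory stress response, and lower transcripts of acinar tissue and of the other endocrine cells. In BTBR ob mice of the same age, beta cell transcripts fell by more than in B6, cholesterol synthesis transcripts rose, and the mitosis list was lower than in lean mice. With an estimated correlation none of these lists passed (adjusted p = 0.10 to 0.76), and without ob mouse 18 the BTBR mitosis list did not. The largest rise in B6 was in Aldh1a3, a retinaldehyde dehydrogenase that is low in healthy beta cells (6.36 ± 0.25, adjusted p = 2.2e-19). The largest in BTBR was in Pate14 (6.60 ± 0.31, adjusted p = 1e-18), and Cck, a gut peptide hormone, rose in both strains (4.38 ± 0.30 in B6 and 5.51 ± 0.30 in BTBR).

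Among cell cycle genes in B6 islets at 10 weeks, 36 of 40 mitosis and G2/M members rose over all genes and 38 adjusted over the list alone, with a median of 0.76 (adjusted p = 2.9e-07; adjusted p = 0.49 with an estimated correlation). The proliferation marker Mki67 rose by 1.38 ± 0.28, Cdca3 by 1.27 ± 0.21, the mitotic kinase gene Aurkb by 1.26 ± 0.27 and Cdc20 by 1.24 ± 0.21. Of 31 DNA replication and G1/S members, 24 rose and 25 did so adjusted over the list alone (median 0.58, adjusted p = 2.8e-08; adjusted p = 0.34 with an estimated correlation). The helicase gene Mcm3 (1.39 ± 0.23), Rrm2 (1.34 ± 0.11), Gins1 (1.25 ± 0.15) and Mcm2 (1.25 ± 0.17) belonged to these. Acinar transcripts moved with these lists: all 22 members of that list fell, also adjusted over the list alone, with a median of -2.64 (adjusted p = 9.1e-15; adjusted p = 0.30 with an estimated correlation). They included the zymogen granule protein Gp2 (-3.31 ± 0.40), colipase Clps (-3.28 ± 0.41), Rnase1 (-3.07 ± 0.42) and Cpa1 (-3.07 ± 0.40). With the acinar score as a covariate, chosen after seeing the data, the mitosis score change went from 0.76 ± 0.19 to 0.33 ± 0.30 while its list kept its side of the threshold (adjusted p = 0.039).

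In BTBR islets at 10 weeks, 14 mitosis and G2/M members fell and 2 rose over all genes, and 11 fell and 2 rose adjusted over the list alone (median -0.40, adjusted p = 0.027; adjusted p = 0.76 with an estimated correlation). Cenpf fell by 1.51 ± 0.33, Pbk by 1.48 ± 0.35 and Cdca8 by 0.99 ± 0.22, while Racgap1, a regulator of cytokinesis, rose by 1.95 ± 0.17. Without BTBR ob mouse 18 this list did not pass (adjusted p = 0.079), and fry gave 0.13 with all mice. The DNA replication and G1/S list of BTBR had 11 members that rose and 1 that fell, 10 and 1 adjusted over the list alone, without passing as a list (median 0.22, adjusted p = 0.078), and passed at 0.023 without mouse 18.

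**Figure D1:**
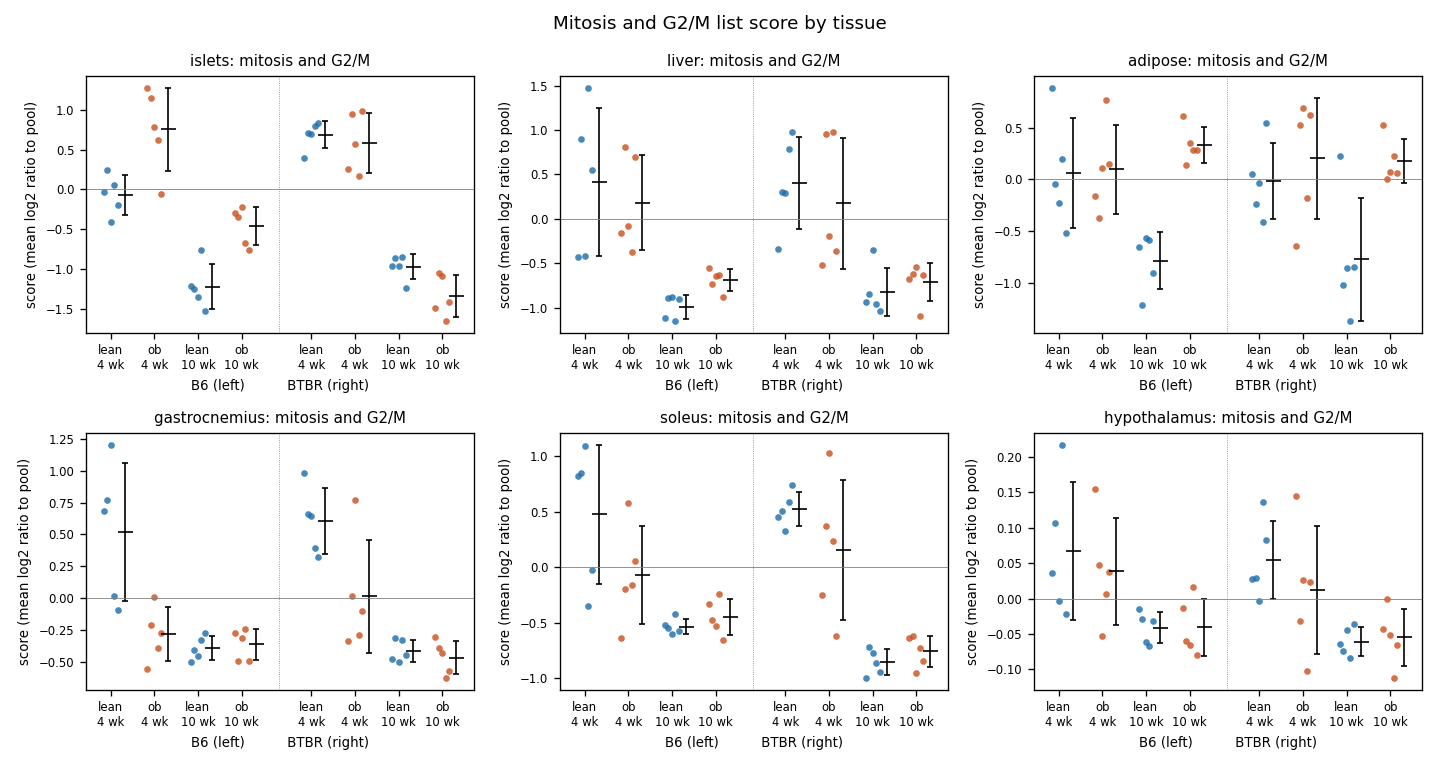
Mitosis and G2/M list score (mean log2 ratio to the pool over the list) per mouse in each tissue, by strain, lean or ob state and age; points are mice, and the bar to their right is the mean with 1 SD, n = 5. In 10-week islets the B6 means are -1.23 for lean and -0.46 for ob mice and the BTBR means -0.98 and -1.34, and lean mice lie lower at 10 than at 4 weeks in all 6 tissues.

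Secretory stress transcripts rose in B6 islets: 12 of 24 members of the ER stress list, also adjusted over the list alone (median 0.36, adjusted p = 0.00031; adjusted p = 0.27 with an estimated correlation). The chaperone genes Sdf2l1 (2.25 ± 0.15) and Dnajc3 (2.23 ± 0.13), Creld2 (1.84 ± 0.16) and Pdia4 (1.41 ± 0.16) were members. Of 42 oxidative phosphorylation members in B6, 28 rose and 2 fell, 28 and 3 adjusted over the list alone (median 0.25, adjusted p = 9.9e-06; adjusted p = 0.32 with an estimated correlation). Ndufa1 (1.36 ± 0.12) stood among these. The oxidative phosphorylation list rose in BTBR as well, with 26 members up and 1 down, 27 and 1 adjusted over the list alone (median 0.23, adjusted p = 3.8e-05; adjusted p = 0.33 with an estimated correlation). The other islet endocrine list had 6 of 8 members that fell in B6, also adjusted over the list alone (median -1.05, adjusted p = 8.9e-07; adjusted p = 0.10 with an estimated correlation). Irx2 (-2.21 ± 0.15), somatostatin Sst (-1.91 ± 0.11), Hhex (-1.86 ± 0.15) and glucagon Gcg (-1.07 ± 0.37) stood among these. In BTBR, 15 of 25 beta cell members fell and 5 rose, also adjusted over the list alone (median -0.57, adjusted p = 0.00026; adjusted p = 0.23 with an estimated correlation). The ion channel gene Trpm5 fell by 3.55 ± 0.20, the beta cell peptide gene Ucn3 by 2.79 ± 0.17, the glucose transporter gene Slc2a2 by 2.32 ± 0.32 and Sytl4 by 2.32 ± 0.24. In B6 8 members of the beta cell list fell and 2 rose, also adjusted over the list alone, without passing as a list (median -0.01, adjusted p = 0.070), and its score changed by -0.33 (exact permutation p = 0.0079). By the strain difference the beta cell list was lower in BTBR in 11 members and higher in 2, 12 and 3 adjusted over the list alone (median -0.44, adjusted p = 0.0048; adjusted p = 0.32 with an estimated correlation). Cholesterol synthesis had 16 of 19 members that rose, also adjusted over the list alone (median 0.79, adjusted p = 1.1e-07; adjusted p = 0.15 with an estimated correlation). Dhcr7 (1.36 ± 0.07) and Lss (1.26 ± 0.09) were among them. Immediate early genes fell in 16 of 17 cases, also adjusted over the list alone (median -1.61, adjusted p = 4.7e-07; adjusted p = 0.32 with an estimated correlation). Fosb (-2.40 ± 0.39), Junb (-2.13 ± 0.25) and Nr4a1 (-2.05 ± 0.29) belonged to these. In B6 9 members of the immediate early response list fell, also adjusted over the list alone (median -0.52, adjusted p = 0.0018; adjusted p = 0.49 with an estimated correlation). Acinar members moved in BTBR as well, 16 of 22 down and 1 up, also adjusted over the list alone (median -1.30, adjusted p = 0.00061; adjusted p = 0.55 with an estimated correlation), as did 5 of 8 duct cell members, all up, also adjusted over the list alone (median 0.44, adjusted p = 0.032; adjusted p = 0.40 with an estimated correlation).

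Further large rises in B6 islets were in Slc35f4 (4.17 ± 0.22), the synaptic protein gene C1ql3 (3.63 ± 0.31), Derl3 of ER-associated degradation (3.37 ± 0.18) and the GABA receptor subunit Gabra4 (3.03 ± 0.33). Large falls were in Tmed11 (-3.88 ± 0.46), the trefoil peptide Tff2 (-3.27 ± 0.41), Pdk4, an inhibitor of pyruvate oxidation (-3.22 ± 0.22), and Fam184b (-3.12 ± 0.24). In BTBR, Tmem252 (5.35 ± 0.49), Radx (5.00 ± 0.18), C1ql3 (4.86 ± 0.31) and Snx31 (4.81 ± 0.36) rose, and Cox6a2 (-4.73 ± 0.40), Rasd1 (-4.60 ± 0.24), Tmem215 (-3.89 ± 0.21), Tff2 (-3.82 ± 0.41) and Tmed11 (-3.62 ± 0.46) fell. Over all genes, 8775 changed in B6 (4836 higher, 3939 lower) and 10276 in BTBR (5150 higher, 5126 lower). Ob and lean values did not overlap in 30.2% and 37.8% of all genes, against 0.794% by chance. At 4 weeks 8983 changed in B6 and 8549 in BTBR.

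The obesity effect itself differed between the strains for 6657 islet genes at 10 weeks (3177 higher in BTBR, 3480 lower) and 1945 at 4 weeks (733 and 1212). The mitosis list was lower in BTBR at 10 weeks in 34 of 40 members and higher in 1, 35 and 1 adjusted over the list alone (median -1.23, adjusted p = 2.8e-10; adjusted p = 0.42 with an estimated correlation). Pbk (-2.39 ± 0.50) and Aurkb (-2.04 ± 0.39) were members. At 4 weeks it was lower in 27 members, 38 adjusted over the list alone (median -0.93, adjusted p = 4.8e-18; adjusted p = 0.32 with an estimated correlation): 37 members rose in B6 (median 0.85), and in BTBR limma called 0 (median -0.08, list adjusted p = 0.48). The acinar score changed by -2.50 in B6 and -1.21 in BTBR at 10 weeks and by -2.40 and -0.87 at 4 weeks. With it as a covariate, the mitosis score difference went from -1.13 to -0.91 and from -0.93 to -0.66. The imprinted growth gene Dlk1 (6.22 ± 0.32), Gdf10 (5.81 ± 0.28), Jakmip3 (4.86 ± 0.18), Pdk4 (4.39 ± 0.31), Spink1 (4.07 ± 0.55) and the prostaglandin receptor Ptger3 (3.97 ± 0.48) had the largest differences towards BTBR. Towards B6 these were Aldh1a3 (-3.46 ± 0.36), Gabra4 (-3.33 ± 0.47), Cox6a2 (-3.15 ± 0.56), Rasd1 (-3.11 ± 0.34), Fam83g (-2.83 ± 0.17) and Tdrd6 (-2.76 ± 0.18). Matrix transcripts were higher in BTBR for 15 of 24 members and lower for 2, 16 and 2 adjusted over the list alone (median 0.73, adjusted p = 5.6e-05; adjusted p = 0.45 with an estimated correlation). Col1a1 (3.06 ± 0.43) was among them. ER stress transcripts were lower for 13 of 24, also adjusted over the list alone (median -0.45, adjusted p = 0.0056; adjusted p = 0.34 with an estimated correlation). Ddit3 (-1.88 ± 0.39) belonged to these.

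With age in lean mice, islet transcripts of cell division and of the extracellular matrix fell. Of 40 mitosis members 38 fell, also adjusted over the list alone (median -1.61, adjusted p = 7e-52; adjusted p = 0.10 with an estimated correlation). Mki67 (-2.28 ± 0.20), Aurkb (-2.23 ± 0.19), Pbk (-2.21 ± 0.25) and Bub1 (-2.15 ± 0.21) were among them. The matrix list had 22 of 24 members that fell, also adjusted over the list alone (median -1.04, adjusted p = 2.9e-37; adjusted p = 0.064 with an estimated correlation), including Col3a1 (-2.28 ± 0.16), Col1a1 (-2.28 ± 0.21) and Lum (-1.71 ± 0.18), and elastin Eln fell by 2.74 ± 0.19. Acinar cell members rose in 15 of 22, 21 adjusted over the list alone (median 0.88, adjusted p = 1.2e-07; adjusted p = 0.41 with an estimated correlation). Reg2 (3.95 ± 0.99), Nupr1 (2.75 ± 0.19), Sycn (1.67 ± 0.28) and the metallothionein Mt1 (1.57 ± 0.15) rose most. Within each strain and obesity class, mitosis members fell in 37 or 38 of 40 cases, with medians of -1.31 in B6 lean, -1.41 in B6 ob, -1.77 in BTBR lean and -2.12 in BTBR ob mice. These 4 calls held with an estimated correlation (adjusted p = 0.020, 0.020, 0.0081 and 0.020). They were adjusted over the 2 cell cycle lists and 4 classes alone, so they cannot be set against the 0.10 above. In all, 4601 genes changed with age (2247 higher, 2354 lower).

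Livers of 10-week B6 ob mice carried higher transcripts of fat synthesis, which BTBR ob mice did not. Transcripts of fat oxidation rose in both strains, and by the strain difference further in BTBR. Transcripts that are normally higher in male livers fell in both strains and those higher in female livers rose. With an estimated correlation none of these lists passed (adjusted p = 0.21 to 0.76). Sult1e1, the oestrogen sulfotransferase, rose far in both strains (6.64 ± 0.50 in B6, adjusted p = 1e-12, and 8.11 ± 0.50 in BTBR, adjusted p = 9.9e-15). Scd1, a fatty acid desaturase, rose by 1.75 ± 0.30 in B6 and fell by 1.47 ± 0.30 in BTBR.

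Of 21 fatty acid and triglyceride synthesis members in B6 liver, 14 rose and 1 fell, 14 and 2 adjusted over the list alone (median 1.65, adjusted p = 4.4e-08; adjusted p = 0.21 with an estimated correlation). Mogat1 of triglyceride assembly (4.76 ± 0.25), Elovl6 (3.42 ± 0.22), Thrsp (3.42 ± 0.34) and fatty acid synthase Fasn (2.95 ± 0.21) belonged to these. In BTBR 2 rose and 3 fell, also adjusted over the list alone, and the list did not pass (median -0.06, adjusted p = 0.48): Mogat1 rose by 4.04 ± 0.25, and Mlxipl (-1.17 ± 0.10) and Fads1 (-0.96 ± 0.16) fell. The difference between the strains covered 15 of 21 members, 16 adjusted over the list alone, all lower in BTBR (median -1.60, adjusted p = 8e-13; adjusted p = 0.13 with an estimated correlation). Fasn (-3.31 ± 0.30) and Scd1 (-3.23 ± 0.43) were members. Cholesterol synthesis rose in B6 in 13 of 19 members, also adjusted over the list alone (median 0.64, adjusted p = 0.00086; adjusted p = 0.69 with an estimated correlation), led by Mvd (1.68 ± 0.19), and by the strain difference was lower in BTBR in 16 of 19, also adjusted over the list alone (median -1.28, adjusted p = 1.3e-10; adjusted p = 0.34 with an estimated correlation). Fatty acid oxidation rose in BTBR in 21 of 24 members and fell in 1, 22 and 1 adjusted over the list alone (median 0.71, adjusted p = 1.3e-07; adjusted p = 0.44 with an estimated correlation). Cyp4a10 (5.01 ± 0.41), Cyp4a14 (4.64 ± 0.33), Vnn1 (2.00 ± 0.33) and Acot2 (1.65 ± 0.24) were members. In B6 11 members of the fatty acid oxidation list rose and 1 fell, 12 and 2 adjusted over the list alone (median 0.21, adjusted p = 0.027; adjusted p = 0.76 with an estimated correlation). The strain difference in it covered 10 members, 13 adjusted over the list alone, all towards BTBR (median 0.44, adjusted p = 5.8e-05; adjusted p = 0.63 with an estimated correlation). The lipid droplet list had 5 of 11 members that rose in B6, also adjusted over the list alone (median 0.35, adjusted p = 0.00017; adjusted p = 0.13 with an estimated correlation). Its genes rose in 9 of 11 cases in BTBR, also adjusted over the list alone (median 1.10, adjusted p = 0.00042; adjusted p = 0.13 with an estimated correlation). Cidec (2.79 ± 0.31), the fatty acid carrier Cd36 (2.69 ± 0.13) and Cidea (1.37 ± 0.18) stood among these.

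Male-biased liver transcripts fell in BTBR ob mice in 11 of 12 members, also adjusted over the list alone (median -4.14, adjusted p = 1.7e-09; adjusted p = 0.26 with an estimated correlation). The urinary protein genes Mup5 (-6.19 ± 0.63) and Mup4 (-5.02 ± 0.57), Ugt2b38 (-5.54 ± 0.70) and the steroid enzyme gene Hsd3b5 (-5.31 ± 0.69) were among them. Female-biased transcripts rose in 10 of 11, also adjusted over the list alone (median 2.81, adjusted p = 7.7e-05; adjusted p = 0.36 with an estimated correlation). The sulfotransferase Sult2a1 (at least 7.52, its lean values lying at or near the lower limit of the scale), Hao2 (5.12 ± 0.50) and A1bg (2.93 ± 0.76) belonged to these. In B6 8 of 12 members of the male-biased liver list fell, also adjusted over the list alone (median -1.79, adjusted p = 0.00016; adjusted p = 0.61 with an estimated correlation). There 7 of 11 of the female-biased liver list rose, also adjusted over the list alone (median 2.06, adjusted p = 0.0021; adjusted p = 0.52 with an estimated correlation). Only the male-biased liver list differed between the strains as a list (median -1.46, adjusted p = 0.00025; adjusted p = 0.62 with an estimated correlation). Probes of the Mup, Sult2a, Cyp2b, Cyp4a and Acot families can cross-hybridise, so single members are uncertain. ER stress transcripts fell in BTBR in 17 of 24 members and rose in 1, also adjusted over the list alone (median -0.50, adjusted p = 1.4e-06; adjusted p = 0.25 with an estimated correlation). Sdf2l1 (-2.43 ± 0.22) and Asns (-1.89 ± 0.25) were members. In B6 15 members of the ER stress and unfolded protein response list fell, 18 adjusted over the list alone (median -0.45, adjusted p = 7.2e-06; adjusted p = 0.28 with an estimated correlation). Interferon response genes fell in BTBR in 16 of 19, also adjusted over the list alone (median -0.84, adjusted p = 6.2e-06; adjusted p = 0.50 with an estimated correlation), including Ifit1 (-1.50 ± 0.32) and Usp18 (-1.27 ± 0.13); the lean BTBR group held mouse 26, whose interferon score was 0.83 against -0.20 to -0.14 in the other 4. The macrophage list fell in 14 of 23 and rose in 1, 15 and 1 adjusted over the list alone (median -0.57, adjusted p = 0.0077; adjusted p = 0.75 with an estimated correlation), with mouse 26 at 0.94 against -0.43 to 0.12.

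**Figure D2:**
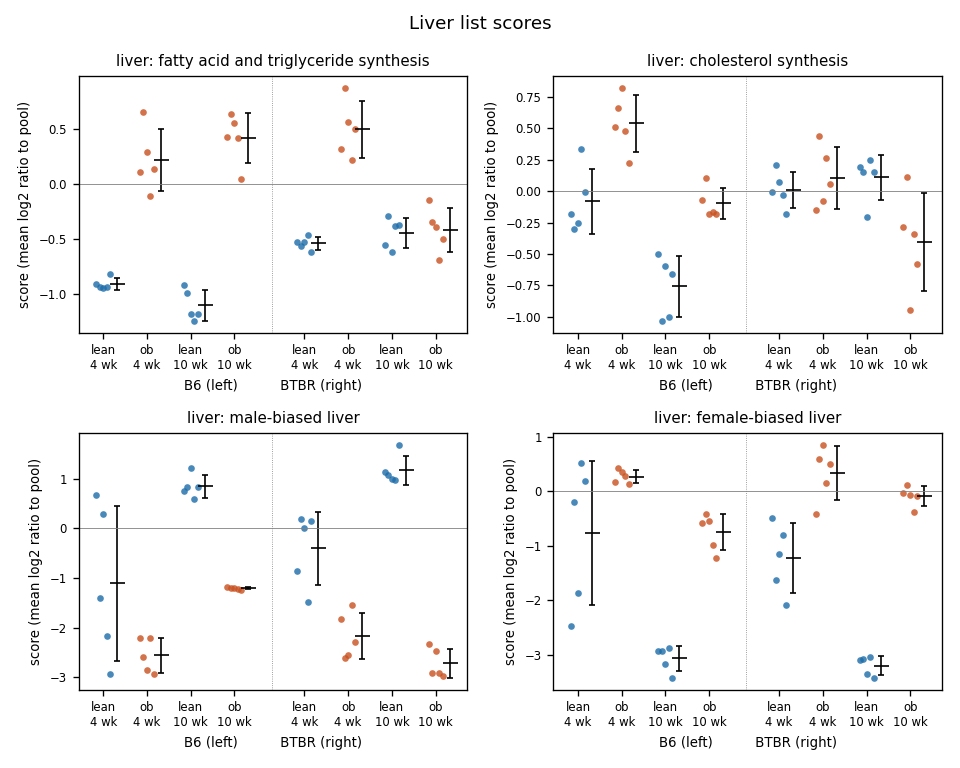
Liver list scores (mean log2 ratio to the pool over the list) per mouse by strain, lean or ob state and age for 2 lipid synthesis lists and the sex-biased lists; points are mice, and the bar to their right is the mean with 1 SD, n = 5. Mean fatty acid and triglyceride synthesis scores at 10 weeks are -1.10 in lean and 0.42 in ob B6 mice, and -0.44 and -0.41 in BTBR mice.

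Other large rises in B6 liver were in the lipid droplet genes Cidea (6.11 ± 0.18) and Cidec (4.93 ± 0.31), Themis (4.67 ± 0.18) and Cyp2b9 (4.27 ± 0.41). The bile acid and hormone carrier Slco1a1 (-5.73 ± 0.56), Tff3 (-5.37 ± 0.44), Hsd3b5 (-5.29 ± 0.69), Hsd3b4 (-4.55 ± 0.62), Scara5 (-4.39 ± 0.54) and the growth factor binding protein Igfbp2 (-4.12 ± 0.23) fell most. In BTBR, Olfr403 (-6.30 ± 0.66) and L1td1 (-4.97 ± 0.48) were among the largest falls. The strains differed towards BTBR in Nnmt (3.91 ± 0.35), Cyp39a1 (3.82 ± 0.42), Cyp4a10 (3.75 ± 0.57) and Cyp4a14 (3.62 ± 0.46), and towards B6 in Olfr403 (-6.25 ± 0.93), Mup5 (-5.71 ± 0.90), L1td1 (-5.21 ± 0.68) and Cidea (-4.73 ± 0.25). By the strain difference fasting and gluconeogenesis genes were higher in BTBR in 9 of 12 members and lower in 1, also adjusted over the list alone (median 1.14, adjusted p = 0.00014; adjusted p = 0.33 with an estimated correlation). Igfbp1 (2.99 ± 0.55) was a member. At 10 weeks 8242 genes changed in B6 (4499 higher, 3743 lower) and 9900 in BTBR (5574 higher, 4326 lower), and 32.1% and 36.5% of all genes did not overlap, against 0.794% by chance. At 4 weeks 5756 and 4645 changed, and Scd1 rose by 2.06 ± 0.30 in B6 and 2.02 ± 0.30 in BTBR. The strains' effects differed for 5088 genes at 10 weeks (2540 higher, 2548 lower in BTBR) and 276 at 4 weeks, of which 32.2% were higher, or 43.0% of 444 after quantile normalization; array weights gave 141, the contrast's own arrays 120, and leaving out B6 lean mouse 47 gave 151.

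Between 4 and 10 weeks in lean mice, liver gained male-biased transcripts and lost female-biased and cell division transcripts. Male-biased members rose in 11 of 12, also adjusted over the list alone (median 1.87, adjusted p = 7.2e-07; adjusted p = 0.39 with an estimated correlation). Elovl3 (3.42 ± 0.48) and C6 (2.85 ± 0.24) stood among these. Female-biased members fell in 9 of 11, also adjusted over the list alone (adjusted p = 2.7e-06; adjusted p = 0.25 with an estimated correlation). Hao2 (-6.33 ± 0.35), Cyp3a44 (-4.67 ± 0.46) and A1bg (-4.35 ± 0.54) were among them. Mitosis members fell in 38 of 40, also adjusted over the list alone (median -1.31, adjusted p = 4.3e-20; adjusted p = 0.39 with an estimated correlation), and the fetal liver gene Afp fell by 0.59 ± 0.13. Obp2a (3.51 ± 0.37), Nox4 (3.30 ± 0.17) and Scara5 (2.90 ± 0.38) also rose, among 6954 genes that changed (3492 higher, 3462 lower). For obesity at 10 weeks the liver mitosis list did not pass in B6 (median 0.28, adjusted p = 0.32) or BTBR (median 0.11, adjusted p = 0.96).

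Adipose tissue of 10-week ob mice carried higher macrophage and cell division transcripts and lower adipocyte transcripts in both strains. With an estimated correlation none of these lists passed (adjusted p = 0.40 to 0.81). Lep itself rose by 2.37 ± 0.23 in B6 and 2.25 ± 0.23 in BTBR; the ob mutation leaves a transcript, so this does not check the labels. Mmp12, a macrophage elastase, rose by 4.82 ± 0.21 in B6 (adjusted p = 3.5e-18) and 4.66 ± 0.21 in BTBR (adjusted p = 4.6e-18), and the adipocyte protease Cfd, or adipsin, changed by -3.44 ± 0.24 and -4.31 ± 0.24. Of 10 lean arrays at this age 6 stood apart (1.52 to 2.83 times the tissue's median deviation), and of ob arrays 0. The farthest, BTBR mouse 33, carried testis transcripts. A fit without such arrays, chosen after seeing the data, rested on lean mice 20 and 48 (B6) and 31 and 32 (BTBR) alone. It kept the macrophage, mitosis and adipocyte calls and gene counts moved by less than 1.5 times.

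Macrophage members rose in 20 of 23 cases in B6 (median 1.70, adjusted p = 1.5e-13; adjusted p = 0.40 with an estimated correlation) and 22 of 23 in BTBR (median 2.32, adjusted p = 1.2e-19; adjusted p = 0.40 with an estimated correlation), with the same counts adjusted over the list alone. They included Trem2 (3.30 ± 0.18) and Lgals3 (2.53 ± 0.14) in B6, Itgax (2.88 ± 0.17 and 3.94 ± 0.17), and the chemokines Ccl2 (3.60 ± 0.41) and Ccl3 (3.01 ± 0.29) in BTBR. Mitosis members rose in 36 of 40 in B6, where 36 rose and 1 fell adjusted over the list alone (median 1.18, adjusted p = 1.3e-07; adjusted p = 0.71 with an estimated correlation), and in 27 of 40 in BTBR, 31 adjusted over the list alone (median 0.98, adjusted p = 2.7e-06; adjusted p = 0.81 with an estimated correlation). Mki67 rose by 1.95 ± 0.35 and 2.33 ± 0.35, Ccna2 by 1.81 ± 0.32 and 2.16 ± 0.32, and Aurkb by 1.88 ± 0.28 and 1.90 ± 0.28. DNA replication and G1/S members rose in 28 and 27 of 31 cases, also adjusted over the list alone (medians 0.76 and 0.69, adjusted p = 6.2e-10 and 9.4e-10; adjusted p = 0.53 in each with an estimated correlation). Adipocyte members fell in 12 of 18 and rose in 2 in B6, also adjusted over the list alone (median -0.55, adjusted p = 8.7e-05; adjusted p = 0.50 with an estimated correlation), and fell in 14 and rose in 1 in BTBR, 15 and 1 adjusted over the list alone (median -0.53, adjusted p = 2e-06; adjusted p = 0.40 with an estimated correlation). Pck1 (-2.98 ± 0.23 and -2.19 ± 0.23) and the hormone gene Retn (-1.72 ± 0.12 and -2.26 ± 0.12) fell in both.

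Matrix members rose in B6 adipose tissue in 16 of 24 cases and fell in 1, 18 and 1 adjusted over the list alone (median 0.56, adjusted p = 1e-06; adjusted p = 0.52 with an estimated correlation). Lox (1.79 ± 0.14) and Timp1 (1.71 ± 0.33) belonged to these. Immediate early genes fell there in 14 of 17, 15 adjusted over the list alone (median -1.26, adjusted p = 5.8e-06; adjusted p = 0.55 with an estimated correlation). Fosb (-3.49 ± 0.62) and Egr1 (-2.57 ± 0.60) were members. In BTBR, 31 of 42 oxidative phosphorylation members fell, 32 adjusted over the list alone (median -0.33, adjusted p = 3.9e-10; adjusted p = 0.55 with an estimated correlation), as did 8 of 21 fatty acid and triglyceride synthesis members, also adjusted over the list alone (median -0.41, adjusted p = 0.00046; adjusted p = 0.55 with an estimated correlation). Mogat1 (-3.10 ± 0.15) and Fasn (-1.92 ± 0.28) were members. Tph2 of serotonin synthesis (5.57 ± 0.31 in B6 and 4.54 ± 0.31 in BTBR) and the macrophage glycoprotein Gpnmb (4.18 ± 0.22 and 4.78 ± 0.22) rose in both strains. Large falls were in Cyp2f2 (-4.63 ± 0.47), Ces1f (-4.36 ± 0.22) and Fam13a (-3.36 ± 0.24) in B6, and in Mup2 (-5.02 ± 0.85), Rprml (-4.12 ± 0.55) and Mup4 (-3.95 ± 0.74) in BTBR. Testis transcripts moved with the B6 comparison: Prm1 (-4.24 ± 1.47), Tnp2 (-3.65 ± 1.31) and 3 more of 16 epididymis and testis members fell, also adjusted over the list alone, without passing as a list (median -0.95, adjusted p = 0.13).

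**Figure D3:**
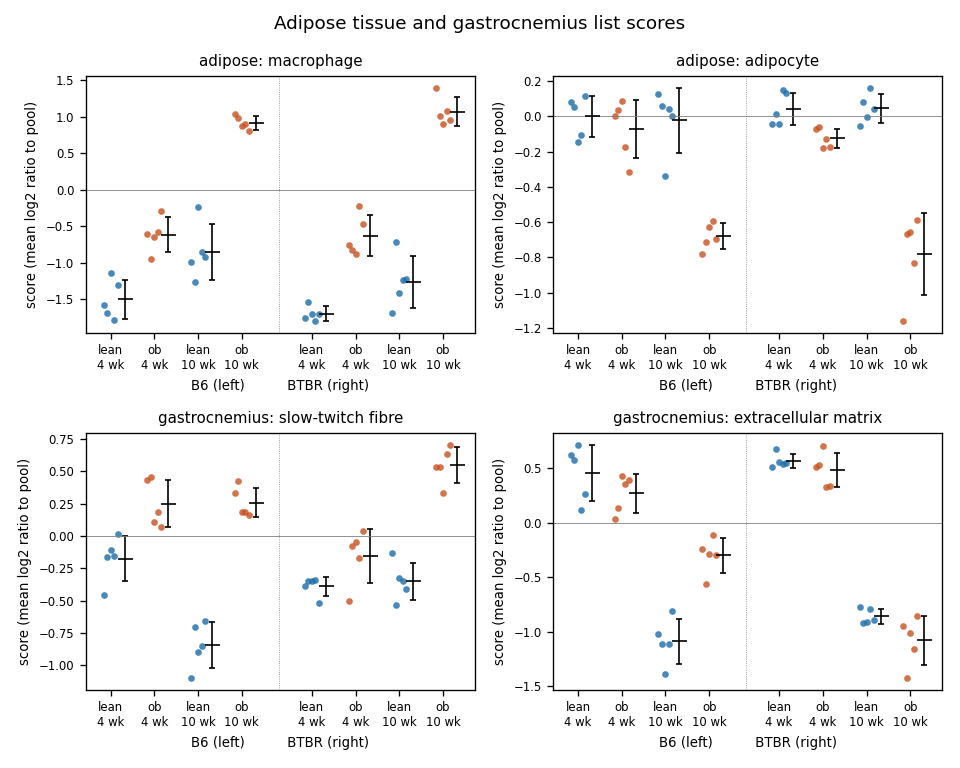
Macrophage and adipocyte list scores in adipose tissue, and slow-twitch fibre and extracellular matrix list scores in gastrocnemius (mean log2 ratio to the pool over the list), per mouse by strain, lean or ob state and age; points are mice, and the bar to their right is the mean with 1 SD, n = 5. At 10 weeks the mean macrophage scores are -0.85 in lean and 0.92 in ob B6 mice and -1.26 and 1.07 in BTBR mice; gastrocnemius matrix scores are -1.09 and -0.30 in B6 and -0.86 and -1.08 in BTBR.

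Over all genes at 10 weeks, 8298 changed in B6 adipose tissue (4652 higher, 3646 lower) and 8760 in BTBR (4511 higher, 4249 lower), and 34.5% and 24.5% of all genes did not overlap, against 0.794% by chance. At 4 weeks the counts were 6596 and 6341, Lep rose by 3.31 ± 0.23 and 2.47 ± 0.23, and thermogenic adipocyte genes rose in BTBR in 6 of 9 members and fell in 1, 7 and 1 adjusted over the list alone (median 1.07, adjusted p = 0.049; adjusted p = 0.81 with an estimated correlation); the lean group held mice 37 and 36, whose arrays stood apart, the first with testis transcripts. Elovl3 (2.71 ± 0.48) and the uncoupling protein gene Ucp1 (2.47 ± 0.71) stood among these. The obesity effect differed between strains for 2570 genes at 10 weeks (1374 higher, 1196 lower in BTBR) and 248 at 4 weeks; array weights gave 5145 and 682, and the latter count was 133 without B6 lean mouse 47 and 165 without BTBR lean mouse 36. Ptgs2 (5.37 ± 1.29), Rnase2a (4.02 ± 0.52) and Ucp1 (3.86 ± 1.01) were higher in BTBR, and Mup2 (-7.86 ± 1.20), Mup4 (-6.30 ± 1.05) and the oxytocin receptor Oxtr (-3.97 ± 0.43) lower. Mesothelial members were higher by the strain difference in 3 of 8, 4 adjusted over the list alone (median 1.26, adjusted p = 0.00036; adjusted p = 0.40 with an estimated correlation). Wt1 (1.78 ± 0.22) belonged to these. With age in lean mice 6085 genes changed (2731 higher, 3354 lower): 34 of 40 mitosis members fell, 36 adjusted over the list alone (median -0.83, adjusted p = 6.5e-12; adjusted p = 0.55 with an estimated correlation), and fatty acid and triglyceride synthesis fell in 18 of 21 members and rose in 1, also adjusted over the list alone (median -0.52, adjusted p = 1.5e-07; adjusted p = 0.40 with an estimated correlation). Elovl6 fell by 2.10 ± 0.31 and Fasn by 1.60 ± 0.20, and Nol3 rose by 2.53 ± 0.14.

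Gastrocnemius of 10-week ob mice carried higher slow-twitch fibre transcripts in both strains. Fatty acid oxidation rose in BTBR alone. Matrix transcripts rose in B6 alone, a call lost at an estimated correlation. Slow-twitch members rose in 10 of 11 in B6, 11 adjusted over the list alone (median 1.13, adjusted p = 5.9e-20; adjusted p = 0.0075 with an estimated correlation), and in 10 of 11 in BTBR, also adjusted over the list alone (median 0.96, adjusted p = 2.8e-11; adjusted p = 0.047 with an estimated correlation). The slow myosin gene Myh7 rose by 2.12 ± 0.18 in B6 and 1.16 ± 0.18 in BTBR, and slow troponin Tnni1 by 1.54 ± 0.14 and 1.15 ± 0.14.

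Fatty acid oxidation members rose in BTBR gastrocnemius in 14 of 24, 15 adjusted over the list alone (median 0.45, adjusted p = 5.5e-14; adjusted p = 0.024 with an estimated correlation). The thioesterase genes Acot1 (3.70 ± 0.22) and Acot2 (2.36 ± 0.13), Pdk4 (1.26 ± 0.25) and Acadl (1.17 ± 0.10) belonged to these. The strain difference in the fatty acid oxidation list covered 13 members, 16 adjusted over the list alone, all higher in BTBR (median 0.45, adjusted p = 1.2e-20; adjusted p = 0.0056 with an estimated correlation). Oxidative phosphorylation members fell in BTBR in 18 of 42 and rose in 1, 22 and 1 adjusted over the list alone (median -0.19, adjusted p = 5.8e-05; adjusted p = 0.58 with an estimated correlation). Ndufc1 (-0.55 ± 0.09) stood among these. In B6, matrix members rose in 20 of 24, 21 adjusted over the list alone (median 0.77, adjusted p = 3.5e-22; adjusted p = 0.050 with an estimated correlation). Col1a1 (2.04 ± 0.26), Col1a2 (1.70 ± 0.21) and Timp1 (1.33 ± 0.23) were members. In BTBR the matrix list did not pass (median -0.32, adjusted p = 0.19). The strain difference in this list covered 18 members, 22 adjusted over the list alone, all lower in BTBR (median -0.93, adjusted p = 7.1e-26; adjusted p = 0.045 with an estimated correlation). Col1a1 (-2.57 ± 0.37) belonged to these. By the strain difference circadian clock genes were higher in BTBR in 4 of 14, 6 adjusted over the list alone (median 0.39, adjusted p = 0.0013; adjusted p = 0.045 with an estimated correlation). Per2 (1.65 ± 0.41) and Cry2 (1.43 ± 0.22) were among them. Adipsin Cfd fell in this muscle (-2.42 ± 0.29 in B6 and -4.31 ± 0.29 in BTBR), as did Cyp2e1 (-1.71 ± 0.30 and -2.27 ± 0.30). Amd1 of polyamine synthesis fell by 3.44 ± 0.34 in BTBR. Embryonic myosin Myh3 rose by 2.23 ± 0.19 and 2.54 ± 0.19 and Mybpc1 by 2.04 ± 0.23 and 2.74 ± 0.23. 

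At 10 weeks 3232 gastrocnemius genes changed in B6 (1628 higher, 1604 lower) and 5008 in BTBR (2363 higher, 2645 lower). Of all genes 15.3% and 21.3% did not overlap, against 0.794% by chance. The strains differed for 1316 (544 higher, 772 lower in BTBR), led by Acot1 (4.51 ± 0.32), Acot2 (2.71 ± 0.19), Pdk4 (2.60 ± 0.35) and Hp (-3.06 ± 0.33). Array weights gave 2641 for this difference and 5392 for B6. At 4 weeks 2863 changed in B6 (1242 with the contrast's own arrays) and 1168 in BTBR (395 to 2070 with 1 mouse left out). The strain difference covered 32 (8 with the contrast's own arrays, 64 with array weights and 53 without arrays that stand apart). Chance was not excluded for the 1168 and the 32. Mitosis members then fell in 34 of 40 in B6, 36 adjusted over the list alone (median -0.76, adjusted p = 1.6e-21; adjusted p = 0.29 with an estimated correlation), including Mki67 (-1.75 ± 0.41), and in 17 in BTBR, 36 adjusted over the list alone (median -0.53, adjusted p = 4.6e-18; adjusted p = 0.34 with an estimated correlation). The share of higher genes in BTBR at 4 weeks was 48.5%, or 59.5% after quantile normalization and 57.3% after centring; a fit on these 10 arrays alone called 85 genes.

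Between 4 and 10 weeks the lean gastrocnemius lost matrix, juvenile growth, developing muscle and cell division transcripts. With an estimated correlation only the matrix and growth lists passed. Matrix members fell in 23 of 24 and rose in 1, also adjusted over the list alone (median -1.48, adjusted p = 4.1e-24; adjusted p = 0.047 with an estimated correlation). Col1a1 (-3.08 ± 0.18) stood among these. Imprinted growth genes fell in 10 of 11, also adjusted over the list alone (median -1.14, adjusted p = 1.4e-11; adjusted p = 0.025 with an estimated correlation). Dlk1 (-2.86 ± 0.14) and Igf2 (-2.65 ± 0.12) were members. Genes of developing or denervated muscle fell in 8 of 10 and rose in 1, also adjusted over the list alone (median -0.65, adjusted p = 2.6e-05; adjusted p = 0.050 with an estimated correlation). Cardiac actin Actc1 (-3.26 ± 0.28) belonged to these. Mitosis members fell in 35 of 40 and rose in 2, also adjusted over the list alone (median -0.90, adjusted p = 1.5e-13; adjusted p = 0.46 with an estimated correlation). Amd1 (2.98 ± 0.24) and Mss51 (2.74 ± 0.25) rose and Cthrc1 (-3.30 ± 0.17) fell, among 10520 genes that changed (6016 higher, 4504 lower).

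Soleus of 10-week BTBR ob mice carried lower transcripts of fast-twitch fibres, oxidative phosphorylation and glycolysis. Fast-twitch members fell in 9 of 11, also adjusted over the list alone (median -0.85, adjusted p = 0.00011; adjusted p = 0.28 with an estimated correlation). Mybpc2 (-2.54 ± 0.54) and fast troponin Tnnt3 (-1.38 ± 0.17) stood among these. Oxidative phosphorylation members fell in 34 of 42, 35 adjusted over the list alone (median -0.38, adjusted p = 2e-13; adjusted p = 0.28 with an estimated correlation), with Ndufc1 at -0.80 ± 0.10, and glycolysis members in 9 of 17, also adjusted over the list alone (median -0.30, adjusted p = 0.0019; adjusted p = 0.28 with an estimated correlation), with the muscle enolase Eno3 at -0.80 ± 0.09. In B6 4 members of the fast-twitch fibre list fell, 5 adjusted over the list alone (median -0.31, adjusted p = 0.031; adjusted p = 0.55 with an estimated correlation). The oxidative phosphorylation list had 5 that fell there, also adjusted over the list alone (median -0.07, adjusted p = 0.041; adjusted p = 0.72 with an estimated correlation). Interferon response members fell in BTBR in 12 of 19, 13 adjusted over the list alone (median -0.55, adjusted p = 6.6e-05; adjusted p = 0.55 with an estimated correlation), with Iigp1 at -2.64 ± 0.45; the lean group held mouse 26, at a score of 1.20 against -0.25 to 0.04.

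In both strains soleus Cfd fell (-3.34 ± 0.41 in B6 and -3.77 ± 0.41 in BTBR) and Myh3 rose (2.38 ± 0.26 and 2.60 ± 0.26). B6 also showed rises in the tachykinin gene Tac4 (2.02 ± 0.16), Slc22a2 (1.93 ± 0.36) and the calcium sensor Casr (1.78 ± 0.20), and falls in fast myosin Myh4 (-3.26 ± 0.90), Cyp2e1 (-3.02 ± 0.52), Cyp2f2 (-2.59 ± 0.54) and Mybpc2 (-2.22 ± 0.54). Muscle atrophy members fell in B6 in 4 of 13, 8 adjusted over the list alone (median -0.45, adjusted p = 0.0021; adjusted p = 0.32 with an estimated correlation). Bnip3 (-0.73 ± 0.17) stood among these. In BTBR, Mybph (4.87 ± 0.39), Ndrg4 (3.39 ± 0.22), Ces5a (3.35 ± 0.21), Rbp4, the retinol carrier (3.02 ± 0.44), and Acot1 (2.87 ± 0.30) rose, and Unc13c (-2.91 ± 0.44), Slc41a3 (-2.49 ± 0.17), Mgst1 (-2.46 ± 0.22) and Kera (-2.39 ± 0.38) fell. Clock genes rose in 8 of 14 and fell in 3, also adjusted over the list alone (median 0.46, adjusted p = 0.030; adjusted p = 0.31 with an estimated correlation). Cry2 (1.64 ± 0.13) was among them. The obesity effect differed between strains for 1444 genes (666 higher, 778 lower in BTBR), with Mybph (4.01 ± 0.54), Angptl4 (3.39 ± 0.37), Unc13c (-3.20 ± 0.62) and Chrna9 (-2.99 ± 0.51) at the ends; quantile normalization gave 772.

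At 10 weeks 3051 soleus genes changed in B6 (1644 higher, 1407 lower; 1955 without lean mouse 23) and 5620 in BTBR (2691 higher, 2929 lower), and 14.4% and 17.2% of all genes did not overlap, against 0.794% by chance. At 4 weeks the counts were 1078 and 1476, with a strain difference for 27 (chance not excluded), and the contrasts' own arrays gave 465, 449 and 6. With age in lean mice 8220 changed (4725 higher, 3495 lower). Of the 10 lean arrays at 4 weeks, 3 stood apart, with liver or kidney transcripts. Mitosis members fell with age in 36 of 40, 37 adjusted over the list alone (median -1.18, adjusted p = 2.7e-20; adjusted p = 0.31 with an estimated correlation). Mki67 (-3.30 ± 0.39) belonged to these. Fatty acid oxidation rose in 16 of 24 and fell in 1, also adjusted over the list alone (median 0.33, adjusted p = 0.00093; adjusted p = 0.45 with an estimated correlation). Acadm (0.85 ± 0.13) was a member. The muscle hormone gene Ostn rose by 2.72 ± 0.14, and Prnd (-3.80 ± 0.36), Cdkn1c (-3.14 ± 0.19) and Myh3 (-2.88 ± 0.18) fell.

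In the hypothalamus of 10-week ob mice the appetite-stimulating peptide genes Agrp and Npy rose in both strains. Agrp rose by 1.18 ± 0.28 in B6 (adjusted p = 0.028) and 2.19 ± 0.28 in BTBR (adjusted p = 1.2e-06), and Npy by 0.58 ± 0.14 and 1.01 ± 0.14. Pomc, the melanocortin precursor, fell by 1.15 ± 0.35 in BTBR and was at -0.80 ± 0.35 in B6 (adjusted p = 0.36). The water balance hormone Avp rose in BTBR by 1.45 ± 0.24.

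Of 17 feeding and neuroendocrine peptide genes in BTBR, 3 rose and 2 fell, also adjusted over the list alone, without passing as a list (median -0.05, adjusted p = 0.71). The insulin-responsive glucose transporter Slc2a4 rose by 0.85 ± 0.16 in B6 and 1.36 ± 0.16 in BTBR, and the cold-induced Rbm3 by 0.53 ± 0.11 and 1.24 ± 0.11. The channel gene Pkd2l1 of fluid-contacting neurons fell by 1.12 ± 0.15 and 0.76 ± 0.15, with H3c15 (-0.99 ± 0.14), Fmo2 (-0.83 ± 0.11) and Rgs1 (-0.79 ± 0.14) in B6 and Egr2 (-0.87 ± 0.28), Fabp7 (-0.86 ± 0.19) and Zfp846 (-0.83 ± 0.07) in BTBR. Cholesterol synthesis fell in BTBR in 9 of 19 and rose in 1, 12 and 2 adjusted over the list alone (median -0.22, adjusted p = 2.6e-05; adjusted p = 0.39 with an estimated correlation), and ER stress members fell in 10 of 24 and rose in 2, 12 and 3 adjusted over the list alone (median -0.12, adjusted p = 0.0047; adjusted p = 0.39 with an estimated correlation), with Creld2 and Sdf2l1 both at -0.71. The cholesterol synthesis list was also lower in BTBR by the strain difference in 5 of 19, 13 adjusted over the list alone (median -0.31, adjusted p = 2.9e-16; adjusted p = 0.030 with an estimated correlation). Red blood cell transcripts moved with this comparison: 5 of 7 rose, also adjusted over the list alone (median 0.91, adjusted p = 0.0018; adjusted p = 0.57 with an estimated correlation), with Hba-a1 at 1.24 ± 0.31, and the near-identical Hbb genes cannot be separated. Angptl4 (1.29 ± 0.14) and Txnip (1.02 ± 0.17) were higher and Npvf (-0.70 ± 0.17) lower in BTBR by the strain difference.

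Counts in hypothalamus were 151 in B6 (60 higher, 91 lower) and 2504 in BTBR at 10 weeks (1263 higher, 1241 lower), and 3.1% and 8.99% of all genes did not overlap, against 0.794% by chance; the B6 count was 84 without ob mouse 1822 and 51 with the contrast's own arrays. At 4 weeks they were 873 and 70, but for B6 only 7 with the contrast's own arrays and 305 without ob mouse 14, which stood apart, and for BTBR 668 with array weights and 17 without ob mouse 16. The strain difference covered 110 genes at 10 weeks (61 higher, 49 lower in BTBR), 62 without BTBR lean mouse 32 and 50 with quantile normalization, while at 4 weeks limma called 0, with 1388 at an unadjusted p under 0.05; array weights gave 24 and separate tests of each probe 4. Higher genes made up 30.0% of the BTBR count at 4 weeks, or 41.9% after quantile normalization, which called 396, and in place of 0 strain differences called 3, 66.7% of them higher. With age in lean mice 3870 genes changed (1610 higher, 2260 lower). Myelin genes fell in 10 of 11, 11 adjusted over the list alone (median -0.61, adjusted p = 4.1e-17; adjusted p = 0.071 with an estimated correlation). Ugt8a (-1.35 ± 0.14) and Cldn11 (-1.23 ± 0.09) stood among these. Matrix genes fell in 17 of 24, 19 adjusted over the list alone (median -0.31, adjusted p = 8.3e-13; adjusted p = 0.25 with an estimated correlation), with Col1a1 (-1.47 ± 0.15), and Abca8a (1.18 ± 0.07) and Il33 (1.07 ± 0.07) rose.

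The obesity effect on the mitosis list in islets was set against that in each other tissue at 10 weeks, with 2-sided exact permutation tests adjusted over the 10 comparisons. In B6 the islet score change (0.76) exceeded that of gastrocnemius by 0.73 (exact p = 0.014, adjusted p = 0.036) and that of hypothalamus by 0.76 (exact p = 0.0079, adjusted p = 0.036). Paired by mouse, both passed as well (exact permutation, adjusted p = 0.040 in each). The differences from liver (0.46, exact p = 0.16), adipose tissue (-0.35, exact p = 0.49) and soleus (0.68, exact p = 0.025, adjusted p = 0.050) did not pass; pairing the tissues by mouse, soleus passed (adjusted p = 0.040). In BTBR the islet change (-0.37) differed from that of adipose tissue by -1.32 (exact p = 0.0014, adjusted p = 0.014). From that of soleus it differed by -0.47 (exact p = 0.013, adjusted p = 0.036); paired by mouse this did not pass (exact permutation, adjusted p = 0.066). By the same exact permutation test liver (-0.48, adjusted p = 0.054), gastrocnemius (-0.32, adjusted p = 0.12) and hypothalamus (-0.37, adjusted p = 0.054) did not pass.

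Of 377 list calls over the 7 comparisons of each tissue, those by age within a class of mice aside, 9 held with an estimated correlation: 8 in gastrocnemius and the cholesterol synthesis difference in hypothalamus. Both strains shared more obesity calls than independent lists would. At 10 weeks 4491 islet genes changed in the same direction in both strains and 1309 in opposite directions; 2439 rose in both, where independent lists give 1251.8, and 2052 fell, where they give 1014.8. Adipose tissue shared 4805 genes in direction with 221 opposed, liver 4763 with 485, gastrocnemius 1732 with 90, soleus 1597 with 64 and hypothalamus 79 with 3. At 4 weeks the shared counts were 5466 in islets with 189 opposed, 4258 in adipose tissue, 2686 in liver, 633 in gastrocnemius, 322 in soleus and 22 in hypothalamus. The strains' comparisons use no common arrays.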

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

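The 3 tests of the islet mitosis pattern and the mislabelling test of mouse 26 were chosen after the result was seen; the tests of the organ transcripts, the lymph node test and the splits of the arrays were written before theirs were run.

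The mitosis and G2/M list was higher in islets of B6 ob mice at both ages, where acinar transcripts were lower; with an estimated correlation the list did not pass (adjusted p = 0.47 at 4 weeks and 0.49 at 10 weeks). Fewer acinar cells in the ob samples would lift every other cell type about equally and is unlikely to be the whole cause, since the list score change exceeded that of the beta cell list by 1.09 or more (exact permutation p = 0.0079 at each age). More immune, endothelial or connective tissue cells are unlikely, since the highest score change among their 4 lists was -0.08, and the authors' scaling of the arrays moved the change by at most 0.031. With the acinar score as a covariate the score change went from 0.83 ± 0.19 to 0.41 ± 0.30 at 4 weeks and from 0.76 ± 0.19 to 0.33 ± 0.30 at 10 weeks, with adjusted p of 0.0039 and 0.039 at the preset correlation. How much of the rise acinar dilution adds stays open, and a biological effect of obesity was not tested apart from it.

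Single arrays carried transcripts of another organ: liver in soleus of lean mice 36 (BTBR) and 31 (B6), kidney in soleus of lean B6 mouse 35, and testis in adipose tissue of lean BTBR mice 33 and 37. A mislabelled sample is unlikely, since the tissue's own marker list fell by 1.02 at most against the group's other mice. A share of RNA or tissue of that organ in the sample stays open: in 5 of 5 arrays the organ's markers lay above every array of the tissue outside the 5, but these arrays were looked at because such transcripts stood out, so that the count decides nothing. Of the markers, 5 of 16 for liver and 7 of 9 for testis also stand in a list tested here, so those lists may carry it. At which step the organ's RNA entered stays open, and no biological explanation was tested.

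Mouse 26, of the lean BTBR group at 10 weeks, had the highest interferon response score of its group in 6 of 6 tissues. A mislabelled sample in 1 tissue is therefore unlikely. Lymph node in the sample stays open, since in 0 tissues did the interferon score stand out while the lymphocyte score lay at or below the mean of the other mice. Deviations of the interferon score were 0.55 in islets, 0.99 in liver, 1.52 in adipose tissue, 1.09 in gastrocnemius, 1.28 in soleus and 0.30 in hypothalamus, beside lymphocyte deviations of 0.69, 0.71, 1.06, 0.38, 0.26 and 0.07, and macrophage deviations of 0.41, 1.14, 0.67, 0.66, 0.63 and 0.00. Macrophage scores were above every other mouse of the group in 5 of 6 tissues, and no biological explanation was tested.

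Splits of the same arrays into mixed groups, 100 for each comparison, tested whether a count could come from chance. At 4 weeks chance was not excluded for the gastrocnemius strain difference, where 32 genes were called and another split gave up to 1531. Nor was it, given the number of comparisons, for BTBR gastrocnemius (2883 against 1168) or the soleus strain difference (165 against 27). In each of these 2, 3 of 100 splits gave as many genes. Such values may reflect single arrays or, untested, a structure of the samples other than the groups. In hypothalamus at 4 weeks limma called 0 (1388 at an unadjusted p under 0.05). Every split reaches that, so the splits (up to 4) decide nothing. For the rest no other split drawn gave as many. Chance could be excluded there at a share of 0.05, with no allowance for the number of comparisons. With 1 mouse left out, 7 of the latter fell under the highest other split: at 4 weeks B6 and BTBR hypothalamus (305 and 17), BTBR soleus (677), B6 gastrocnemius (2075) and the strain differences of liver (151) and adipose tissue (133), and at 10 weeks that of adipose tissue (2099). The called count and that split for B6 and BTBR at 10 weeks were 8775 and 5175, 10276 and 5427 in islets, 8242 and 4144, 9900 and 5119 in liver, 8298 and 3901, 8760 and 6088 in adipose tissue, 3232 and 527, 5008 and 2184 in gastrocnemius, 3051 and 477, 5620 and 2856 in soleus, and 151 and 66, 2504 and 350 in hypothalamus. At 4 weeks they were 8983 and 4247, 8549 and 5303 in islets, 5756 and 1683, 4645 and 1778 in liver, 6596 and 4510, 6341 and 3600 in adipose tissue, 2863 and 2393 in B6 gastrocnemius, 1078 and 536, 1476 and 1278 in soleus, and 873 and 671, 70 and 18 in hypothalamus. For age they were 4601 and 1406 in islets, 6954 and 3134 in liver, 6085 and 4741 in adipose tissue, 10520 and 5938 in gastrocnemius, 8220 and 1686 in soleus and 3870 and 1506 in hypothalamus. For the strain difference at 4 weeks the highest other values were 346 in islets, 204 in liver and 163 in adipose tissue, and at 10 weeks 2952, 950 and 2184 in these, 27 in gastrocnemius, 58 in soleus and 23 in hypothalamus.

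Cell cycle scores of 3 mice stood outside their group, of 96 groups and lists looked at, where about 1 in 20 would do so by chance. In liver the mitosis score of lean BTBR mouse 26 at 10 weeks was -0.35, the others lying between -1.03 and -0.85, and that of BTBR ob mouse 18 was -1.09, the others lying between -0.67 and -0.54. In gastrocnemius the G1/S score of BTBR ob mouse 13 at 4 weeks was 0.23, the others lying between -0.06 and 0.02. Over all lists 89 of 1176 (7.57%) did so.

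A strain difference was called, at 4 and 10 weeks, for 1945 and 6657 genes in islets, 276 and 5088 in liver, 248 and 2570 in adipose tissue, 32 and 1316 in gastrocnemius, 27 and 1444 in soleus, and for 110 in hypothalamus at 10 weeks. Chance was not excluded for the 32 and the 27. Lists that differed numbered 6 and 16 in islets, 8 and 9 in liver, 8 and 7 in adipose tissue, 9 and 10 in gastrocnemius, 4 and 12 in soleus, and 7 and 7 in hypothalamus. With an estimated correlation 3 of these remained in gastrocnemius and 1 in hypothalamus, all at 10 weeks, and 0 in the other tissues. In islets the median strain difference was -0.70 and -0.42 for the DNA replication and G1/S list and -0.93 and -1.23 for the mitosis and G2/M list. The mitosis effect of islets minus another tissue at 10 weeks was 0.73 for gastrocnemius and 0.76 for hypothalamus in B6, and -1.32 for adipose tissue and -0.47 for soleus in BTBR.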

How the results depend on the processing

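The fit without the arrays that stand apart and the acinar covariate were chosen after the result was seen; every other setting was fixed before. The direction of the ratio rests on the pool argument and on marker genes, and each group has 5 mice. No batch is named, and signal over background is not given in the sources used here. Over all settings and left-out mice, 764 values of gene counts lay within 1.5 times of the reported count and 116 moved. Of single named genes, 12377 values kept their call, 305 became weaker and 34 stronger; of list tests 1939 kept it, 144 became weaker and 51 stronger, and no named gene or list turned its direction.

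Without the less variable genes, counts were 5960, 5598, 5703 and 6400 in islets (B6 and BTBR at 4 weeks, then at 10), and 3730 for the strain difference at 10 weeks. In liver they were 3805 for B6 at 4 weeks, 4845 and 5470 for B6 and BTBR at 10 weeks, 3119 for the strain difference at 10 weeks and 4120 for age. In adipose tissue they were 3850, 3582, 5104 and 5642 in the order given for islets and 3628 for age; for age they were 6169 in gastrocnemius and 5141 in soleus. These are lower because fewer genes were tested.

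With only the groups of the contrast, fewer samples give the spread. Counts were 2712 for BTBR liver at 4 weeks and 120 for its strain difference, 5727 for BTBR adipose tissue at 10 weeks and 157 for the strain difference at 4 weeks. At 4 weeks they were 1242 for B6, 85 for BTBR and 8 for the difference in gastrocnemius, and 465, 449 and 6 in soleus. In hypothalamus they were 7 for B6 and 1 for the difference at 4 weeks, and 51 for B6, 1568 for BTBR and 64 for the difference at 10 weeks.

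Array weights gave strain differences at 4 weeks of 141 in liver, 682 in adipose tissue, 64 in gastrocnemius, 70 in soleus and 24 in hypothalamus, and at 10 weeks of 5145 in adipose tissue, 2641 in gastrocnemius and 2339 in soleus. They also gave 5392 for B6 gastrocnemius at 10 weeks, and 2491 in soleus and 668 in hypothalamus for BTBR at 4 weeks. Quantile normalization gave strain differences of 444 in liver and 3 in hypothalamus at 4 weeks, and 772 in soleus and 50 in hypothalamus at 10 weeks, with 444 for B6 and 396 for BTBR at 4 weeks and 257 for B6 at 10 weeks in hypothalamus. Array median centring gave 377 for the strain difference in adipose tissue at 4 weeks, and tests of each probe gave 13 in soleus and 4 in hypothalamus. Without the arrays that stand apart, the strain difference at 4 weeks was 53 in gastrocnemius and 12 in soleus, and B6 hypothalamus at 4 weeks had 305. The cause was not tested.

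With an estimated correlation, list calls went from 79 to 0 in islets, 73 to 0 in liver, 58 to 0 in adipose tissue, 63 to 8 in gastrocnemius, 61 to 0 in soleus and 43 to 1 in hypothalamus, where fry gave 23. Cell cycle calls by age in the 4 classes of mice went from 8 to 5 in islets, 7 to 0 in liver, 6 to 0 in adipose tissue, 4 to 0 in gastrocnemius, 7 to 0 in soleus (3 with fry) and 5 to 0 in hypothalamus. For islets, adjusted p of the mitosis and G2/M list with an estimated correlation was 0.47 for B6 at 4 weeks, 0.49 for B6 and 0.76 for BTBR at 10 weeks (0.13 with fry), 0.32 and 0.42 for the strain difference at 4 and 10 weeks, and 0.10 for age. For the DNA replication and G1/S list it was 0.32 and 0.34 for B6 at 4 and 10 weeks, 0.19 and 0.55 for the strain difference, and 0.11 for age. The cause was not tested.

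For islets minus soleus at 10 weeks in B6, adjusted p by exact permutation was 0.050 without a block, 0.040 with the mouse as a replicate block (paired by mouse), 0.039 with the median of members and 0.047 with centring; in BTBR the replicate block gave 0.066 in place of 0.036. For islets minus hypothalamus in BTBR it was 0.039 with the median of members and 0.047 with centring, in place of 0.054. Genes that changed in both strains in the same direction by at least 2-fold numbered, at 4 and 10 weeks, 288 and 352 in islets, 90 and 190 in liver, 227 and 527 in adipose tissue, 15 and 36 in gastrocnemius, 14 and 35 in soleus and 0 and 1 in hypothalamus. The share of probes below 0 turned to the other side of 50% for the top 50 in BTBR gastrocnemius (32.0%) and BTBR hypothalamus (42.0%), and for the top 1000 in B6 hypothalamus (71.0%).

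Leaving out 1 mouse at a time, the islet mitosis list of BTBR at 10 weeks had adjusted p of 0.0078 to 0.079, the highest without ob mouse 18, and the G1/S list 0.023 to 0.13, the lowest without ob mouse 18. In liver the strain difference at 4 weeks ran from 151 to 385: 175 without B6 ob mouse 10, 154 without ob 5, 151 without lean 47, and in BTBR 182 without lean 42, 165 without lean 37 and 172 without ob 16. In adipose tissue it ran from 133 to 352: 165 without BTBR lean mouse 36 and 133 without B6 lean 47. BTBR gastrocnemius at 4 weeks ran from 395 to 2070: 570 and 718 without lean mice 37 and 36, and 584, 2070, 395 and 746 without ob 15, 13, 16 and 12. In soleus, B6 at 10 weeks ran from 1955 (without lean mouse 23) to 3203, and B6 at 4 weeks from 665 (without ob 7) to 1271, with 701 without lean 47. BTBR soleus at 4 weeks ran from 677 to 1719: 888 and 981 without lean mice 41 and 42, 828 and 677 without ob 12 and 16.

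The strain difference in soleus at 4 weeks ran from 9 to 61. In BTBR it was 17, 10, 17 and 13 without lean mice 41, 42, 37 and 45, and 46, 14, 10 and 13 without ob 15, 11, 12 and 16. In B6 it was 15, 11, 10 and 61 without lean mice 45, 47, 31 and 34, and 12, 12, 13 and 9 without ob 7, 14, 10 and 11. In hypothalamus B6 at 4 weeks ran from 305 to 1726: 349, 1726, 567 and 345 without lean mice 31, 34, 35 and 45, and 1450, 305, 468 and 565 without ob 5, 14, 7 and 11. BTBR at 4 weeks ran from 17 to 93: 38, 17 and 33 without ob mice 12, 16 and 11, and 20, 22 and 27 without lean 36, 45 and 37. B6 at 10 weeks ran from 84 to 175: 90, 91 and 97 without lean mice 48, 22 and 20, and 92 and 84 without ob 1823 and 1822. The strain difference ran from 0 to 4 at 4 weeks (4 without B6 ob mouse 7, 1 without B6 lean 35) and from 62 to 149 at 10 weeks (62 without BTBR lean 32, 68 without B6 lean 23). The cause was not tested.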

Other observations

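The criterion for arrays that stand apart was chosen after the result was seen, and the organ markers were looked at for arrays that had drawn attention. In islets of 10-week B6 ob mice, transcripts of connective tissue and of macrophages were lower than in lean mice. Extracellular matrix members fell in 13 of 24 cases, also adjusted over the list alone (median -0.34, adjusted p = 0.0018; adjusted p = 0.55 with an estimated correlation), among them the collagen-binding Dcn (-2.13 ± 0.26) and Lum (-1.85 ± 0.25) and the collagen gene Col1a1 (-1.25 ± 0.30). Macrophage members fell in 10 of 23 and rose in 3, 11 and 3 adjusted over the list alone (median -0.37, adjusted p = 0.010; adjusted p = 0.48 with an estimated correlation), with Ctss (-1.06 ± 0.15) and the growth factor receptor Csf1r (-0.81 ± 0.14). Acinar transcripts fell in the same comparison. Fatty acid oxidation members were higher in BTBR by the strain difference in 11 of 24 cases and lower in 1, 12 and 2 adjusted over the list alone (median 0.29, adjusted p = 0.00052; adjusted p = 0.30 with an estimated correlation), with Pdk4 (4.39 ± 0.31), Acot1 (3.13 ± 0.23) and the nuclear receptor gene Ppara (2.30 ± 0.18). The list of genes low in healthy beta cells has a median of -0.60 and a mean of 0.22 in B6 islets at 4 weeks, and -0.38 and 0.14 at 10 weeks, and its test runs downward.

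In soleus at 4 weeks the mitosis list passed as lower in ob mice only with a preset correlation, in B6 (median -0.57, adjusted p = 2.3e-11; adjusted p = 0.55 with an estimated correlation) and BTBR (median -0.33, adjusted p = 3.7e-05; adjusted p = 0.65 with an estimated correlation). Over all genes limma called 0 of its 40 members in either strain, and adjusted over the list alone it called 4 in B6; fry gave 0.075 and 0.27. The lean groups there held the 3 soleus arrays that stood apart, with liver or kidney transcripts. Between 4 and 10 weeks in adipose tissue of lean mice, 19 of 40 mitosis members fell in B6 and 18 in BTBR (medians -0.86 and -0.78; adjusted p = 0.34 in each with an estimated correlation). In ob mice the list did not pass (median 0.22, adjusted p = 0.16 in B6, and median -0.05, adjusted p = 0.92 in BTBR), and of 31 DNA replication and G1/S members 10 rose and 1 fell in B6 and 11 and 2 in BTBR (adjusted p = 0.00046 and 0.0064; 0.54 and 0.61 with an estimated correlation); the difference between lean and ob mice was not tested.

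Cholesterol synthesis was lower in BTBR adipose tissue at 10 weeks by the strain difference in 6 of 19, 8 adjusted over the list alone (median -0.47, adjusted p = 3.1e-05; adjusted p = 0.55 with an estimated correlation), with Insig1 (-1.29 ± 0.37) and Dhcr7 (-1.23 ± 0.28).

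Organ markers of single arrays, as the median deviation from the group's other mice, were 5.00 for liver in soleus of BTBR mouse 36, with Fabp1 at 7.55, and 3.95 in soleus of B6 mouse 31, where arrays without a named organ reached 3.06. Kidney markers were at 3.48 in soleus of B6 mouse 35, with Kap at 8.88, against at most 0.24 elsewhere. Testis markers were at 4.54 and 5.77 in adipose tissue of BTBR mice 33 and 37, with Prm1 at 7.69 in the latter, against at most 3.80 elsewhere. Arrays that stand apart from their group by more than 1.5 times the usual spread numbered 9 in adipose tissue, 2 in gastrocnemius, 3 in soleus and 1 in hypothalamus.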
